A study of Mus musculus with 2 samples.

How the data were processed

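Single-cell RNA libraries from Balb/c mouse brain were analysed, 2 in all and 1 per group. The cells had been loaded on a microfluidic chip of the Singleron GEXSCOPE kit, per the labels' protocols, which captures single cells and marks each molecule with a unique molecular identifier (UMI). The groups were taken from the sample titles, control and positive. The treatment field contradicts the titles, since it gives metastasis of 4T1, a mouse mammary carcinoma line of triple-negative type, to the library titled control and its absence to the library titled positive. Groups are therefore named by title only and no direction with or without metastasis was drawn.

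The deposited matrices hold raw UMI counts per gene and barcode, and the submitters' processing notes name Cell Ranger, without a version, and the genome build GRCm38. The annotation release, the calling of cells and the strand setting of the counting are not given in the sources used here. The deposited counts were used as they stand, and genes with no UMI in a library were absent from its gene list. The libraries listed 26248 genes (titled control) and 26129 genes (titled positive), and 23160 genes were in both lists. Coordinates came from GENCODE M21 on GRCm38, in which 29170 of the 29217 gene identifiers were found. Counts of overlapping or antisense genes, of pseudogenes and of the H2 genes, a family of near-identical copies that also differs between mouse strains, are uncertain, since reads could be split or assigned to another member.

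Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept, and doublets called per library by the Scrublet method of scanpy were removed. The filter left out 11 barcodes of the titled control library and 5 of the titled positive library, and 600 barcodes (5.77%) and 300 barcodes (2.77%) were called doublets. The kept cells numbered 9806 and 10537. Counts were scaled to 10000 per cell and log-transformed for clustering only, and Leiden clustering at resolution 1 was run on 30 principal components of 2000 variable genes with 15 neighbours. This gave 33 clusters, of which 8 that matched more than 1 class were clustered again, giving 62 clusters and sub-clusters.

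Classes were named from markers of 23 cell types fixed before the data were examined, and carry "like" because no annotation of cells was used here. A class needed a mean log2 marker ratio of at least 1.5 over the median cluster and at least 3 markers detected. A cluster was called mixed when a second class scored within 1.5 of the first, had at least 50% of its own markers detected and reached at least 60% of the first class's share of detected markers. It was also called mixed when markers of another class outnumbered its own among its 10 leading genes. These thresholds were set after the clusters had been seen, and a cluster with a close second score but fewer of that class's markers kept its name. The 20 mixed clusters held 4.86% of the titled control cells and 0.873% of the titled positive cells.

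With 1 library per group there was no test between conditions, no p-value and no count of changed genes, and each difference has no replicate check. Shares are given with exact Clopper-Pearson 95% intervals. UMIs were summed over the cells of a class and scaled to the class total as CPM with exact Poisson 95% intervals, and log2 ratios of titled positive over titled control used a pseudocount of 0.5 counts with conditional exact binomial intervals. All intervals cover counting error only. A gene with 100 counts in a class sum had an interval of 81.4 to 122 counts, and the class sums compared ran from 349384 UMIs (titled control T cell-like cells) to 23633690 UMIs (titled control oligodendrocyte-like cells). A level of 0 was compared with a floor of 3 counts in the class sum of that library. Of the classes, 6 had at least 50 cells in each library and were compared.

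Gene lists were fixed before the data were examined. For each list the median log2 ratio over genes with at least 10 UMIs was set against 10000 random lists matched on mean expression, and its interval came from 1000 Poisson draws of the counts. Members of a list were counted as higher or lower by the sign of their ratio, and the number whose interval included 0 is given where there were any. The pairs of list and class that the text reports were chosen by what the class is known for, after the medians had been seen. Neutrophil lists in oligodendrocyte-like cells and MHC class II genes in T cell-like cells were added later, for comparison. Where the median log2 ratio of all genes with at least 50 UMIs in both libraries differed from 0 by more than 0.1, list medians are also given relative to it.

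The genes named were fixed by rule before the data were examined. In the oligodendrocyte-like class, the largest in the smaller of its libraries, they were the 10 genes with the highest and the 10 with the lowest log2 ratio among genes with at least 100 UMIs in the higher library, and in each of the next 4 classes the 5 highest and 5 lowest. Markers of other cell types and mitochondrial, haemoglobin, immunoglobulin and sex-linked genes were left out. Of each list, the members with the largest and smallest ratio and the most abundant member were named, as were the markers that name a class. Some genes that meet these rules are not reported here by name.

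RNA released from broken cells enters all droplets or wells. Its share in each class was estimated from the markers of the most abundant other class of the library, and subtracting it was an alternative added after the data had been examined, as were shares among cells other than carcinoma-like ones. An earlier upper limit on that share was removed, and genes with 3 or fewer counts left in both libraries were given no value, also after the values had been seen. Doublets that were not called raise the markers used for this estimate. An estimated share can therefore also hold their RNA, which the subtraction cannot tell apart from free RNA. The other alternatives were fixed before the data were examined. They covered the filter on cells (500 genes and 10% mitochondrial, or none), no doublet removal, resolutions of 0.5 and 2, naming each cell by its own markers, shares without unnamed, mixed and erythroid-like cells, median-of-ratios scaling, the mean of per-cell CPM, cells thinned to 1000 UMIs, free RNA at 5%, totals without mitochondrial and ribosomal genes, and list minimums of 1 and 50 UMIs.

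Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The ratio and list steps were tested on simulated data. For class sums of the microglia-like class over 13958 genes, the 54 genes simulated at a log2 ratio of 2 had a median of 2.00 and the 49 genes at -2 a median of -2.03, and the intervals held the true ratio for 95.8% of genes.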

Results

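Gene expression was measured in single cells of Balb/c mouse brain in a model of breast cancer metastasis to the brain, to compare the brain's cell types between a library titled control and a library titled positive. The titled control library held 10417 barcodes with 55657687 UMIs, and the titled positive library 10842 barcodes with 98141261 UMIs. Median depth per barcode was 4230 UMIs and 1723 genes in the titled control library and 7383.5 UMIs and 2472 genes in the titled positive library. The lowest barcode held 2270 UMIs in the former and 3160 in the latter, so cells with less RNA can be missing from both. There was 1 library per group, so no difference was set against replicate spread.

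Carcinoma-like cells, which carried the epithelial genes Epcam, Krt8 and Krt18, made up 55.7% of the titled positive library (95% interval 54.8 to 56.7%, 5871 of 10537 cells) and 1 of 9806 cells in the titled control library (0.0102%, 0.000258 to 0.0568%). When each cell was named by its own markers, 21 titled control cells (0.214%) were carcinoma-like. Monocyte or macrophage-like cells were 21.1% in the titled positive library (20.3 to 21.9%) and 2.05% in the titled control library (1.78 to 2.35%). Neutrophil-like cells were 2.65% against 0.112%, and T cell-like cells 2.78% against 0.887%. At clustering resolution 2 the 279 titled positive neutrophil-like cells became 175 (1.66%), against 0.102% in the titled control library. Carcinoma markers stood at 46.1% of the carcinoma-like level in titled positive neutrophil-like cells. Brain-resident classes had lower shares in the titled positive library. Oligodendrocyte-like cells were 7.96% there and 35.7% in the titled control library, microglia-like cells 6.09% and 24.3%, and astrocyte-like cells 0.199% (21 cells) and 19.5% (1915 cells). The microglia-like share depended on the processing, since the 642 titled positive cells became 192 (1.77%) without doublet removal and 270 (2.56%) when each cell was named by its own markers, against 2359 and 2173 titled control cells.

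Vessel-associated classes followed the same order, with endothelial cell-like cells at 1.02% and 5.35%, pericyte-like cells at 0.0569% and 2.04%, and smooth muscle cell-like cells at 0.0664% and 1.56% in the titled positive and titled control library. Among immune cells alone, microglia-like cells were 18.5% of 3476 cells in the titled positive library and 88.1% of 2700 in the titled control library, and monocyte or macrophage-like cells 64.01% and 7.44%. Among all cells other than carcinoma-like ones, oligodendrocyte-like cells were 17.98% and 35.7%, and astrocyte-like cells 0.450% and 19.5%. Fibroblast-like cells were 0.683% against 0.979% of all kept cells. This order turned among cells other than carcinoma-like ones (1.54%, 1.21 to 1.94%, against 0.979%, 0.794 to 1.19%) and when each cell was named by its own markers. The shares come from libraries with the depth gap and UMI minimums given above, and most clusters belonged to 1 library.

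**Figure D1:**
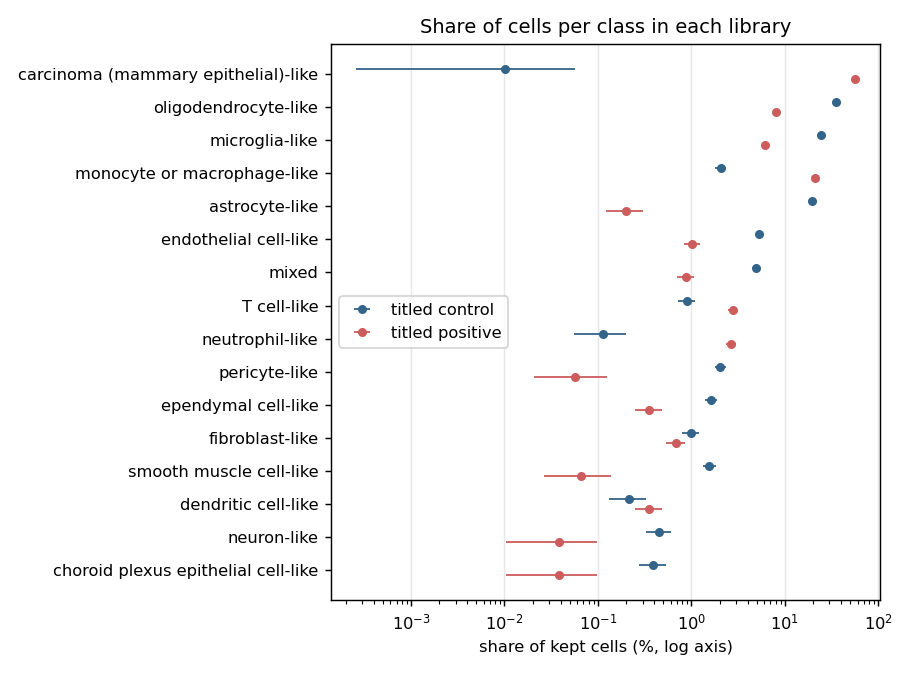
Share of kept cells in each class (percent, log axis) in the library titled control and the library titled positive. Points are shares and bars are exact 95% binomial intervals, which cover counting error only. Carcinoma-like cells were 55.7% of the titled positive and 0.0102% of the titled control library.

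Counted without clusters, cells with UMIs of at least 3 of the 11 carcinoma markers were 76.9% of the titled positive library and 3 of 9806 cells (0.0306%) in the titled control library. Of the titled positive cells outside the carcinoma-like class, which should lack these genes, 48.5% also met it (median depth 5204 UMIs), against 99.4% of the class itself (median 10225 UMIs). Thinned to 1000 UMIs, 5.66% of the cells outside the class and 69.6% of the class met it. In the titled control library 0 of 9806 cells did, which allows up to 0.0306% at the floor of 3 cells and 0.0376% by the exact interval. Genes per cell at that depth had medians over all kept cells of 637 in the titled positive and 621 in the titled control library, against 2447 and 1687 unthinned, and no cell was left out. By class the ratio ran from 0.905 in oligodendrocyte-like cells (555 and 613 genes) to 1.05 in T cell-like cells (646 and 614).

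Oligodendrocyte-like cells, the myelin-forming cells of the brain, had much higher levels of interferon-response and antigen-presentation genes in the titled positive library. All 11 MHC class I genes, which present peptides to T cells, were higher, with a median log2 ratio of 5.64 (95% counting interval 5.61 to 6.15; 5.83 relative to all genes), as were all 16 type I interferon response genes (5.21, 5.14 to 5.52; 5.39 relative) and all 7 MHC class II genes (4.54, 4.37 to 4.67; 4.72 relative). H2-D1 was at 171 CPM in the titled control and 8553 CPM in the titled positive library, H2-T23 at 7.49 and 1988 CPM, and Ifi27l2a at 32.6 and 1092 CPM. The smallest ratio among the interferon genes was that of the transcription factor Stat2, at 18.4 and 132 CPM. These medians lay at percentiles 100, 100 and 99.99 of random lists. Lists of neutrophil genes were higher in this class too. All 9 neutrophil granule genes were higher (4.91, 4.40 to 6.30; 5.09 relative; percentile 99.99), from Camp (3.11) to Chil3 (8.61). So were all 10 mature and inflammatory neutrophil genes (4.23, 3.65 to 4.79; 4.42 relative; percentile 100), 1 with an interval that included 0. The MHC class II median therefore does not stand apart from lists of other cells' genes. The median over all genes in this class was -0.19.

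Of the 10 genes with the highest ratios in these cells, 6 were higher there than in carcinoma-like cells. They were Arg1, Iigp1, an interferon-induced GTPase (GRCm38 chromosome 18, 60376027 to 60392634), Gm12250 (chromosome 11, 58187739 to 58189012), F830016B08Rik, Serpina3h and BC023105. Iigp1 was at 0.423 CPM in the titled control and 1547 CPM in the titled positive library (95% interval 1511 to 1584), against 392 CPM in carcinoma-like cells, and Gm12250 at 0.296 and 726 CPM against 83.8. F830016B08Rik was at 0 and 82.4 CPM (at least 649-fold higher), Serpina3h at 0 and 41.6 CPM (at least 328-fold) and BC023105 at 0 and 23.5 CPM (at least 185-fold). The annotation lists Gm12250, Serpina3h and BC023105 as pseudogenes, so their counts are uncertain. Wfdc2, Msln and Prkg2 were most abundant in carcinoma-like cells. Wfdc2 was at 312 CPM in titled positive oligodendrocyte-like and 2926 CPM in carcinoma-like cells, Msln at 44.8 and 363 and Prkg2 at 36.3 and 392. Arg1 was at 39.9 CPM, against 32.8 in carcinoma-like and 1710.3 in monocyte or macrophage-like cells.

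Among the 10 lowest genes, Slc7a10, Slc6a11, Cldn10, Btbd17, Gria1 and AW047730 were most abundant in astrocyte-like cells of the titled control library, and Gkn3 in endothelial cell-like cells. Slc7a10, an amino acid transporter, was at 14.8 CPM in titled control oligodendrocyte-like cells and 929.9 CPM in titled control astrocyte-like cells, Slc6a11 at 21.03 and 664, Cldn10 at 36.7 and 2322, and Gkn3 at 7.36 CPM against 1564 in endothelial cell-like cells. E330034G19Rik (9.69 and 0 CPM, at least 14.4-fold lower) and Gm4524 (6.18 and 0 CPM, at least 9.20-fold lower) were highest in the oligodendrocyte-like class itself, and the annotation lists Gm4524 as antisense. Gpr176 was at 4.91 and 0 CPM (at least 7.31-fold lower).

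Myelin genes were mostly lower in the titled positive library, 6 of 8, with a median log2 ratio of -0.95 (-0.97 to -0.93; -0.76 relative; percentile 2.06), though all of them also name the class. Opalin was at 1086 CPM in the titled control and 249 CPM in the titled positive library, while Mobp was at 4994 and 6137 CPM. All 14 dissociation and immediate early genes were higher (median 2.13, 2.01 to 2.32; 2.32 relative; percentile 100), with Fos at 48.9 and 482 CPM and Atf3 at 4.15 and 58.7 CPM. All 14 nuclear genes of oxidative phosphorylation were lower (median -0.53, -0.57 to -0.50; -0.34 relative; percentile 24.7), such as Cox4i1 at 1360.0 and 944 CPM and Atp5e at 511 and 264 CPM. Glycolysis and hypoxia genes were higher for 10 of 14 (median 0.47, 0.38 to 0.55; 0.65 relative; percentile 99.74). The list ran from Car9 at 0.0846 CPM (2 UMIs) and 12.8 CPM, a log2 ratio of 6.93 (5.32 to 10.32), down to Ndrg1 at 882 and 250.1 CPM. Proliferation genes were higher for 12 of 14 (4.63, 4.19 to 5.02; 4.81 relative; percentile 100), with Cdk1 at 0.508 and 40.3 CPM against 375 in carcinoma-like cells. Intervals included 0 for 1 of 14 proliferation, 1 of 14 oxidative phosphorylation and 1 of 14 glycolysis genes.

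The class came from clusters 1 and 5 in the titled control library and cluster 8 in the titled positive library, and the latter held carcinoma markers at 11.98% of the carcinoma-like level, while titled control oligodendrocyte-like cells held microglia markers at 1.34% of the microglia-like level. With the estimated free RNA subtracted (16.1% of the titled positive and 6.49% of the titled control class RNA), the median was 6.97 for interferon, 7.30 for MHC class I, 9.95 for MHC class II and 4.26 for immediate early genes, and -0.11 for glycolysis and hypoxia genes, which turned the direction of the last. The proliferation median also turned, to -0.54 over the 8 genes with counts left. With free RNA at 5% the first 4 medians were 6.48, 6.54, 7.91 and 3.49. Subtraction can take titled control counts to 0, where a ratio rests on the pseudocount of 0.5 counts. The estimated share also raised the neutrophil granule median in this class, from 4.91 to 9.10 over the 4 genes with counts left. A higher median after subtraction therefore does not show that a signal is independent of free RNA.

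**Figure D2:**
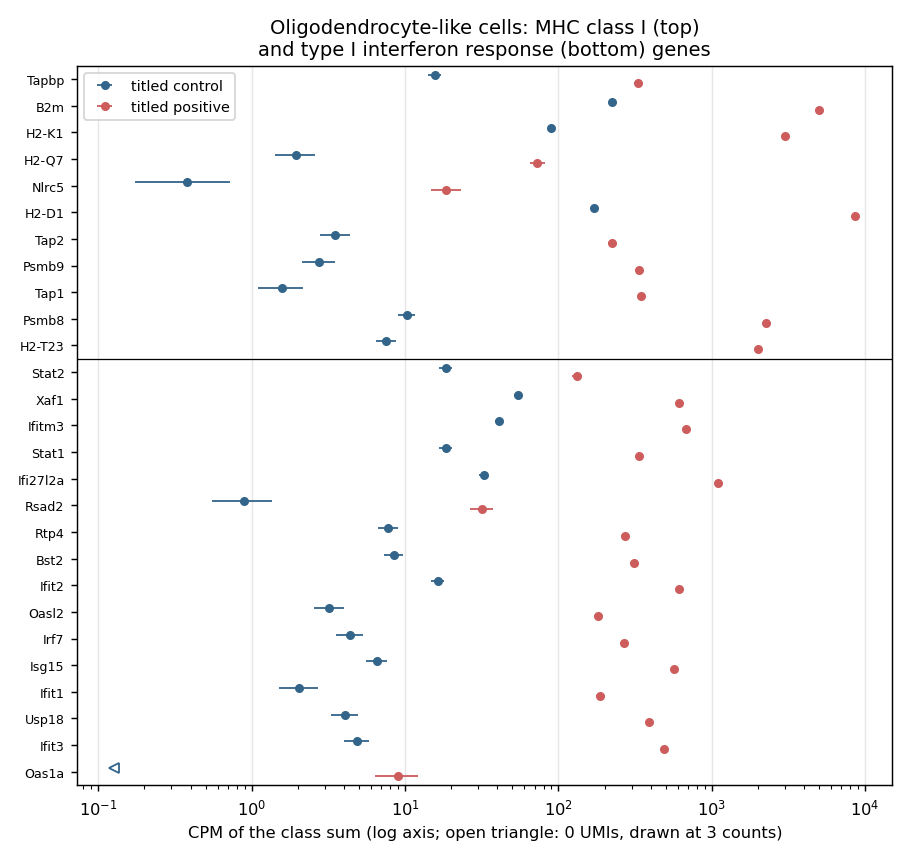
CPM (log axis) of MHC class I and type I interferon response genes in oligodendrocyte-like cells of the library titled control and the library titled positive, with exact 95% Poisson intervals for counting error. An open triangle marks a gene with 0 UMIs, drawn at 3 counts. Every gene shown lies higher in the titled positive library, H2-D1 at 8553 against 171 CPM.

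Microglia-like cells, the resident macrophages of the brain, had lower levels of every homeostatic gene and higher levels of antigen-presentation genes in the titled positive library. All 15 homeostatic genes were lower, with a median log2 ratio of -3.04 (-3.19 to -2.89; -2.91 relative to all genes, whose median was -0.13), below all random lists. It was -2.46 without doublet removal, with 192 titled positive cells in place of 642. The purinergic receptor gene P2ry12 was at 6339.9 CPM in the titled control and 309 CPM in the titled positive library, a log2 ratio of -4.36 (-4.45 to -4.27). Tmem119 was at 1597 and 269, Fcrls at 472 and 5.01, and Csf1r at 4411 and 1705. Of the list, 10 genes also name the class, and the median over the 5 that do not was -3.04. Within each library all 15 genes were higher in microglia-like than in monocyte or macrophage-like cells, with a median log2 ratio of 3.44 in the titled control and 2.52 in the titled positive library. For the 10 that name the class this was largely fixed by the naming. Of the 5 others, Slc2a5 was at 0 CPM in monocyte or macrophage-like cells of both libraries, so no size is given for it. In microglia-like cells it was at 35.4 CPM in the titled control and 1.95 CPM in the titled positive library. The rest ran from 1.95 (Csf1r) to 4.39 (Sparc) in the titled control library. In the titled positive library they ran from 0.87 (Tgfbr1) to 3.30 (Sparc).

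All 7 MHC class II genes were higher (median 6.05, 5.99 to 6.11; 6.18 relative; percentile 100), with the invariant chain gene Cd74 at 277 CPM in the titled control and 18355 CPM in the titled positive library. So were all 11 MHC class I genes (2.41, 2.32 to 2.48; 2.54 relative; percentile 100), with B2m at 4597 and 9797 CPM, and all 16 interferon genes (2.27, 2.09 to 2.38; 2.40 relative; percentile 100), with Ifitm3 at 226 and 2307 CPM. Disease-associated microglia genes went both ways, 14 of 20 being higher (median 0.83, 0.69 to 0.95; 0.96 relative; percentile 99.98). Apoe was at 7919.6 and 27895 CPM and Gpnmb at 0 and 16.7 CPM (at least 49.8-fold higher), while the protease gene Ctsd was at 12958 and 3363 CPM. Chemokine and cytokine genes were higher for 12 of 17 (1.13, 0.95 to 1.25; 1.26 relative; percentile 99.97), such as Ccl12 at 1125 and 4838 CPM and Cxcl9 at 5.02 and 276 CPM, while Il6 was at 9.37 and 0.834 CPM. Proliferation genes were higher for 13 of 14 (1.47, 1.34 to 1.60; 1.60 relative; percentile 100), with Rrm2 at 9.49 and 47.3 CPM. The proliferation median was 1.17 with the estimated free RNA subtracted (15.9% of the titled positive and 9.20% of the titled control class RNA), 0.26 without doublet removal, 2.20 with mean per-cell CPM and 2.21 when thinned to 1000 UMIs. Dissociation and immediate early genes were lower for 12 of 14 (-1.28, -1.35 to -1.19; -1.15 relative; percentile 0.0200), with Zfp36 at 3607 and 1775 CPM, while Nr4a1 was at 107 and 209 CPM. Intervals included 0 for 1 of 20 disease-associated and 1 of 17 chemokine genes.

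Of the 5 highest genes in this class, the receptor gene Klrb1b (chromosome 6, 128813706 to 128826331) was at 0 and 44.8 CPM (at least 134-fold higher), and at 59.1 CPM in titled positive dendritic cell-like cells. Il1r2, a decoy receptor for interleukin 1, was at 0.223 CPM (2 UMIs) and 307 CPM, a log2 ratio of 10.10 (8.57 to 13.47), against 913 CPM in monocyte or macrophage-like cells. Arg1 was at 0 and 59.5 CPM against 1710.3 in the same class, Wfdc2 at 0.223 and 287 CPM against 2926 in carcinoma-like cells, and BC100530 at 0 and 40.6 CPM against 8434 in neutrophil-like cells. Among the 5 lowest, the transporter gene Abcb4 (chromosome 5, 8893717 to 8959231) was highest in microglia-like cells of the titled control library, at 33.6 CPM and 0 in the titled positive library (at least 40.3-fold lower). Cldn10, Ednrb, Nkain4 and Lsamp were most abundant in titled control astrocyte-like cells, Cldn10 at 2322 CPM there and 54.7 CPM in microglia-like cells. The class came from clusters 2, 15.1, 15.2 and 15.6 in the titled control and cluster 10 in the titled positive library, which scored 2.18 for microglia and 2.01 for monocyte markers. Carcinoma markers were at 11.8% of the carcinoma-like level in the titled positive class, and oligodendrocyte markers at 4.68% of the oligodendrocyte-like level in the titled control class.

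Monocyte or macrophage-like cells, 201 in the titled control and 2225 in the titled positive library, had higher levels of tumour-associated macrophage and glycolysis genes in the latter. The class was made up of different clusters in each library, as given below. Arg1, which encodes the arginine-degrading enzyme arginase 1 (chromosome 10, 24915221 to 24927484), was at 11.2 CPM in the titled control (95% interval 5.58 to 19.99) and 1710.3 CPM in the titled positive library (95% interval 1689 to 1732). It was found in 1 titled control cell (0.498%) and 77.3% of titled positive cells. Tumour-associated macrophage genes were higher for 10 of 14, with a median of 1.49 (1.08 to 1.91; 1.63 relative to all genes, whose median was -0.14; percentile 100), and 1.67 without the 3 that name the class. The scavenger receptor gene Cd163 was lower, at 65.01 and 8.40 CPM, and Apoe was at 24103 and 21629 CPM. All 14 glycolysis and hypoxia genes were higher (1.55, 1.41 to 1.67; 1.69 relative; percentile 100), from Vegfa, which drives vessel growth, at 12.2 and 152 CPM, to Hk2 at 40.6 and 62.9 CPM.

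All 11 MHC class I genes were higher in this class (1.19, 1.01 to 1.33; 1.33 relative; percentile 99.98), with Tap1 at 89.4 and 305 CPM. MHC class II genes had a median of 0.026 (-0.012 to 0.18; 0.17 relative; percentile 37.97), with Cd74 at 14787 and 14168 CPM. Interferon genes had a median of 0.28 (0.17 to 0.45; 0.42 relative; percentile 92.3), with 11 of 16 higher, while Ifi27l2a was at 2583 and 907 CPM. Chemokine and cytokine genes split, 9 higher and 8 lower (median 0.039, -0.31 to 0.21; 0.18 relative; percentile 42.6). Cxcl9 was at 16.3 and 506 CPM and Ccl5 at 832 and 4348 CPM, while Ccl3 was at 1453 and 298 CPM. Proliferation genes were higher for 13 of 14 (1.43, 1.06 to 1.62; 1.58 relative; percentile 100), with Rrm2 at 6.10 and 28.8 CPM. Dissociation and immediate early genes split, 8 higher and 6 lower (0.23, 0.13 to 0.33; 0.37 relative; percentile 75.5), with Fos at 1267 and 2022 CPM. Intervals included 0 for 1 of 14 immediate early, 1 of 14 glycolysis, 2 of 7 MHC class II, 4 of 16 interferon, 2 of 17 chemokine and 4 of 14 proliferation genes.

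The highest genes in the class besides Arg1 included Il1r2 (chromosome 1, 40074079 to 40125231) at 3.05 CPM (3 UMIs) and 913 CPM, a log2 ratio of 8.004 (6.68 to 10.50). Gbp11 was at 0 and 105 CPM (at least 34.3-fold higher), Mrap at 0 and 80.3 CPM (at least 26.4-fold) and Wfdc2 at 0 and 279 CPM against 2926 in carcinoma-like cells. The lowest were Clec4b1 at 153 and 1.09 CPM, Adgre4 at 125 and 1.16, Il12b, a subunit of interleukin 12, at 153 and 2.25 CPM, and Cbr2, itself a border macrophage marker, at 372 and 4.56 CPM. All 151 titled control UMIs of Il12b came from 1 cell, and 0.629% of titled positive cells held the gene, so its ratio rests on that cell. Gpr37l1 was at 144 and 1.96 CPM against 5631 in titled control astrocyte-like cells. Different clusters held the class, most other parts of cluster 15 in the titled control and clusters 6 and 7 in the titled positive library, where carcinoma markers stood at 10.4% of the carcinoma-like level. Clec4b1 and Cbr2 were among the leading genes of a part of cluster 15 with 91 titled control cells and 1 titled positive cell. Adgre4 was among those of another part, with 43 titled control and 0 titled positive cells. The low ratios of these genes therefore cannot be told apart from the near absence of such cells in the titled positive class. Subtracting the estimated free RNA (14.02% of the titled positive and 8.11% of the titled control class RNA) gave 0.82 for proliferation and 0.092 for interferon genes. With the stricter filter on cells the MHC class II median was 1.40 and the chemokine median -0.0071, and the latter was 0.87 with mean per-cell CPM and -0.10 with a minimum of 50 UMIs.

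Endothelial cell-like cells, 525 in the titled control and 108 in the titled positive library and all in 1 shared cluster, had lower levels of blood-brain barrier genes and higher levels of activation and matrix genes in the titled positive library. Blood-brain barrier genes were lower for 11 of 12 (median -0.77, -0.90 to -0.66; percentile 0.0600), with the tight junction gene Cldn5 at 3095 and 1654 CPM and the transferrin receptor gene Tfrc at 481 and 90.7 CPM, while the glucose transporter gene Slc2a1 was at 1734 and 2295 CPM. Activation and angiogenesis genes were higher for 9 of 13 (0.91, 0.79 to 1.03; percentile 99.98), with Lrg1 at 216 and 2311 CPM, while Plvap was at 30.9 CPM and, with 1 UMI, 1.09 CPM, a log2 ratio of -4.24 (-10.14 to -2.31). Extracellular matrix genes were higher for 9 of 10 (1.41, 0.99 to 1.73; percentile 99.98), with Thbs1 at 0 and 12.03 CPM (at least 11.8-fold), while Sparc was at 3533 and 3100.3 CPM. Thbs1 was at 33.7 CPM in carcinoma-like cells and 38.6 CPM in the pooled other titled positive cells. RNA of other cells at the estimated share of 36.1%, free or in doublets that were not called, could therefore account for its level here. The matrix median was 1.25 after subtraction of that share, over the 8 genes with counts left. Ubd, which encodes a ubiquitin-like protein induced by interferon gamma (chromosome 17, 37193892 to 37196095), was at 0 in the titled control and 2109.8 CPM in the titled positive library (95% interval 2017 to 2206), at least 2073-fold higher, against 24.6 CPM in carcinoma-like cells. It was found in 33.3% of titled positive endothelial cell-like cells.

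MHC class II genes were higher for all 7 (4.34, 3.999 to 4.53; percentile 99.99), with Cd74 at 98.4 and 2116 CPM. T cell-like cells had a similar median (4.51), so expression by endothelial cell-like cells themselves was not settled. MHC class I genes were higher for 10 of 11 (0.90, 0.64 to 1.02; percentile 99.94), while B2m was at 8438 and 8408 CPM, and interferon genes for 14 of 16 (0.60, 0.48 to 0.79; percentile 99.95), with Ifitm3 at 3806 and 6954 CPM. Dissociation and immediate early genes were higher for 12 of 14 (0.58, 0.47 to 0.70; percentile 99.73), with Fos at 869 and 1600.4 CPM. Proliferation genes were higher for 13 of 14 (4.58, 3.85 to 5.38; percentile 100; 4.66 with genes at 0 set to the floor). Their median was 0.92 after subtraction of the estimated free RNA, over 12 genes, 2.20 with a minimum of 50 UMIs, 3.68 when thinned and 3.68 without doublet removal. Intervals included 0 for 1 of 14 proliferation, 2 of 14 immediate early, 2 of 13 activation, 1 of 10 matrix, 2 of 11 MHC class I and 4 of 16 interferon genes. Besides Ubd, the highest genes were all more abundant elsewhere in the titled positive library. BC100530 was at 339 CPM against 8434 in neutrophil-like cells. Msln, Top2a and Prkg2 were at 186, 138 and 120.3 CPM against 363, 319 and 392 in carcinoma-like cells. Of the lowest, Alpl, a phosphatase gene (chromosome 4, 137741733 to 137796384), was at 100.4 and 0 CPM (at least 30.6-fold lower) and at 349 CPM in titled control fibroblast-like cells. Cldn10, Tril, Fabp7 and S100b were most abundant in titled control astrocyte-like or oligodendrocyte-like cells, Fabp7 at 3738 CPM in astrocyte-like and 53.3 CPM in endothelial cell-like cells. Carcinoma markers stood at 26.8% of the carcinoma-like level in these titled positive cells, and the barrier median was -0.30 after subtraction of the estimated free RNA (36.1% of the titled positive and 9.08% of the titled control class RNA) and -0.41 without doublet removal. After the same subtraction the MHC class II median was 3.24, over the 3 genes with counts left, and it was 5.03 with free RNA at 5%. Thinned to 1000 UMIs the medians were 3.50 for MHC class II, 0.70 for matrix and 1.71 for activation genes, and the last was 1.75 with mean per-cell CPM.

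T cell-like cells, 87 in the titled control and 293 in the titled positive library and all in 1 shared cluster, had higher levels of checkpoint and regulatory genes in the titled positive library and lower levels of naive or memory genes. NK cells were not separated from T cells in it. Markers of NK cells gave its second score (2.92, against 5.41 for T cells), and 54 titled control and 181 titled positive cells were T cell-like when named by their own markers, so the cytotoxicity and granzyme values below cannot be assigned to T cells alone. Checkpoint receptor genes were higher for 7 of 9 (median 1.40, 0.77 to 2.19; 1.52 relative to all genes, whose median was -0.12; percentile 100), with Icos at 135 and 165 CPM, while Tox was at 28.6 and 7.29 CPM. Tigit was at 2.86 CPM (1 UMI) and 27.8 CPM, a log2 ratio of 2.71 (0.75 to 8.61). All 6 regulatory T cell genes had ratios above 0, 4 of them with intervals above 0 (2.21, 1.77 to 2.84; 2.33 relative; percentile 100), with Tnfrsf18 at 71.6 and 249.7 CPM. Tnfrsf4 was at 5.72 CPM (2 UMIs) and 296 CPM, a log2 ratio of 5.37 (3.83 to 8.74). Naive and memory genes were lower for 6 of 7 (-1.37, -1.97 to -1.07; -1.24 relative; percentile 0.0200), with the transcription factor Tcf7 at 109 and 9.11 CPM and Il7r at 146 and 83.4 CPM. T and NK cytotoxicity genes were lower for 7 of 10 (-0.84, -1.07 to -0.63; -0.72 relative; percentile 0.170), with the chemokine gene Ccl5 at 10624 and 1472 CPM, while Ifng was at 83.003 and 381 CPM.

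Gzmc, which encodes a granzyme (chromosome 14, 56231441 to 56234656), was at 0 in titled control and 960.2 CPM in titled positive T cell-like cells (95% interval 919.7 to 1002), at least 112-fold higher, and at 2.25 CPM in carcinoma-like cells. Only 14.3% of titled positive T cell-like cells held it, so the level comes from a small part of the class. The other highest genes, Wfdc2, Spp1, Lcn2 and Atf3, were at 1203, 1571, 843 and 188 CPM here and 2926, 3262, 2369 and 330.1 CPM in carcinoma-like cells. The lowest, S100b, Sparcl1, Tubb4a, Sept4 and Cryab, were most abundant in titled control oligodendrocyte-like or astrocyte-like cells, Sparcl1 at 18454 CPM in astrocyte-like and 352 CPM in titled control T cell-like cells. Proliferation genes had a median of 0.31 (0.10 to 0.48; 0.43 relative; percentile 92.6), with 10 of 14 higher, while Hmgb2 was at 1379.6 and 795 CPM. MHC class I genes had a median of 0.14 (0.058 to 0.32; 0.26 relative; percentile 67.4), with H2-D1 at 6454 and 6866 CPM. All 7 MHC class II genes were higher (4.51, 3.88 to 5.67; 4.63 relative; percentile 100), from H2-DMa (2.14) to Cd74 (5.71). Their median was 5.09 with the gene at 0 set to the floor. It lay near the endothelial cell-like (4.34) and oligodendrocyte-like (4.54) medians, and whether any of these classes expressed the genes itself was not settled. Interferon genes had a median of 0.70 (0.50 to 1.18; 0.83 relative; percentile 99.91), with Ifitm3 at 195 and 2024 CPM, and 0.84 with genes at 0 set to the floor. Dissociation and immediate early genes were higher for 12 of 14 (0.72, 0.58 to 1.13; 0.85 relative; percentile 99.76; 0.92 with the gene at 0 set to the floor), with Fos at 258 and 782 CPM. Intervals included 0 for 3 of 14 immediate early, 1 of 9 checkpoint, 1 of 7 naive and memory, 2 of 10 cytotoxicity, 7 of 14 proliferation, 4 of 11 MHC class I and 7 of 16 interferon genes. Carcinoma markers stood at 39.9% of the carcinoma-like level in titled positive T cell-like cells, and oligodendrocyte markers at 9.95% of the oligodendrocyte-like level in titled control ones. With the estimated free RNA subtracted (53.7% of the titled positive and 19.7% of the titled control class RNA), the interferon median turned to -0.17, the cytotoxicity median was -0.064, the checkpoint median 2.57 and the regulatory median 2.99. The checkpoint median was 3.20 when thinned and 2.46 with mean per-cell CPM, which also gave 0.89 for proliferation genes. The estimated titled positive share was 53.7% here, 36.1% in endothelial cell-like and 62.3% in neutrophil-like cells. Their median depths were 5602, 6734 and 6966 UMIs. In microglia-like cells the share was 15.9% at 4902.5 UMIs. RNA that enters all droplets or wells alike would not give larger shares at greater depth. Part of the larger shares can therefore be RNA of carcinoma-like cells in doublets that were not called, which was not tested.

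Fibroblast-like cells, 96 in the titled control and 72 in the titled positive library, had higher matrix and chemokine gene levels in the titled positive library. All 13 extracellular matrix genes were higher (median 2.92, 2.83 to 3.26; percentile 100), with Sparc at 2036 and 15427 CPM, Tnc, which encodes tenascin C, at 0 and 1239 CPM (at least 216-fold higher) and Col4a1 at 109 and 223 CPM. The median was 1.81 without the 3 genes that name the class. Chemokine and cytokine genes were higher for 12 of 13 (2.39, 1.94 to 3.54; percentile 100), with Cxcl9 at 0 and 510.2 CPM (at least 88.8-fold). Ccl7 was at 3.83 CPM (2 UMIs) and 1037 CPM, a log2 ratio of 7.76 (6.22 to 11.13). Interferon genes were higher for 14 of 15 (1.47, 1.13 to 1.66; percentile 100), with Ifit2 at 13.4 and 94.1 CPM. All 10 MHC class I genes were higher (1.28, 1.19 to 1.40; percentile 99.83), with Tap1 at 26.8 and 193 CPM. Dissociation and immediate early genes were higher too, all 13 of them (1.74, 1.48 to 2.15; percentile 100), with Fos at 149 and 1382 CPM. Proliferation genes were higher for 12 of 14 (4.85, 4.37 to 6.09; percentile 100), with Cdk1 at 0 and 184 CPM against 375 in carcinoma-like cells. Their median was 3.99 with genes at 0 set to the floor, 3.87 when thinned and 4.84 after subtraction of the estimated free RNA. Intervals included 0 for 2 of 14 proliferation, 3 of 13 chemokine, 1 of 13 immediate early, 1 of 15 interferon and 1 of 10 MHC class I genes. The class was mostly a different cluster in each library, which the comparison cannot separate from a change within the same cells. Of the 96 titled control cells 75 were in cluster 23, and of the 72 titled positive cells 44 were in cluster 29, which held no titled control cell and was led by collagen genes. Titled positive fibroblast-like cells held carcinoma markers at 10.7% of the carcinoma-like level. After subtraction of the estimated free RNA (14.4% of the titled positive and 5.92% of the titled control class RNA) the chemokine median was 4.44. It was 4.32 with free RNA at 5%, 3.58 when thinned, 4.30 with a minimum of 50 UMIs and 2.25 with genes at 0 set to the floor.

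Ribosomal protein genes had positive medians in all 6 compared classes, 0.29 in oligodendrocyte-like, 0.63 in microglia-like, 0.23 in monocyte or macrophage-like, 0.35 in endothelial cell-like, 0.27 in T cell-like and 0.29 in fibroblast-like cells. They lay at percentiles 99.82, 94.5, 63.5, 93.9, 86.1 and 80.4 of random lists. Of the 14 genes, 10, 14, 14, 14, 11 and 13 were higher, and 3 in oligodendrocyte-like, 3 in T cell-like and 1 in fibroblast-like cells had intervals below 0. Relative to all genes the medians were 0.48, 0.76, 0.38, 0.33, 0.40 and 0.38, and with the estimated free RNA subtracted the oligodendrocyte-like median turned to -0.75. Rpl32 was at 665 and 1183 CPM in titled control and titled positive oligodendrocyte-like cells and at 2329 and 4808 CPM in microglia-like cells, while carcinoma-like cells held 5193 CPM. Mitochondrial transcripts had medians of -0.41, -0.0084, -0.10, -0.075, 0.25 and -1.001 in the same order, at percentiles 52.95, 28.8, 12.4, 34.6, 75.1 and 1.88. Relative to all genes these were -0.22, 0.12, 0.042, -0.10, 0.38 and -0.90, so the sign in microglia-like and monocyte or macrophage-like cells flipped with the scaling. The microglia-like interval (-0.027 to 0.011) included 0, and that median was also above 0 with mean per-cell CPM (0.054), thinning (0.056), totals without mitochondrial and ribosomal genes (0.062) and a minimum of 1 UMI (0.19). Setting genes at 0 in 1 library to the floor gave 0.59 for endothelial interferon genes and -0.11 for monocyte or macrophage mitochondrial transcripts, and medians equal to 2 decimals for the other reported lists with such genes, oligodendrocyte, microglia and monocyte or macrophage interferon (5.21, 2.27 and 0.28), disease-associated microglia (0.83), endothelial activation (0.91) and matrix (1.41), and fibroblast matrix genes (2.92). In fibroblast-like cells mt-Cytb was at 16414 CPM in the titled control and 8824 CPM in the titled positive library. Not all 9 mitochondrial transcripts of the list were measured, with 8 in oligodendrocyte-like, 6 in microglia-like and 7 in monocyte or macrophage-like cells. In carcinoma-like cells mt-Co2, mt-Co3 and mt-Atp6 held 27, 26 and 81 UMIs, against 901607 for mt-Cytb. They were also rare in the pooled other titled positive cells (0.442, 0.306 and 0.918 CPM), so mitochondrial values rest on the other transcripts.

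**Figure D3:**
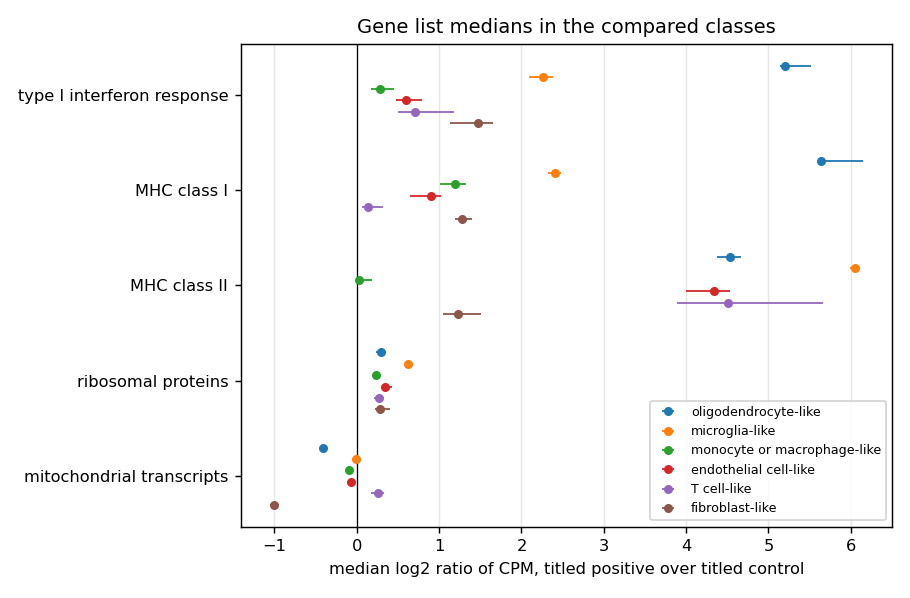
Median log2 ratio of CPM, titled positive over titled control, of 5 gene lists in the 6 compared classes. Bars are 95% intervals for counting error. MHC class I medians run from 0.14 in T cell-like to 5.64 in oligodendrocyte-like cells, and ribosomal protein medians from 0.23 to 0.63.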

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

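The tests of lost carcinoma cells, of library preparation and of monocytes among microglia-like cells were chosen after the result was seen, and the subtraction of the estimated free RNA was added after the data had been examined but before its effect was known, although an upper limit on the share was dropped later. Barcodes called doublets, left out of every comparison, mostly carried carcinoma markers in the titled positive library. Of the 300 barcodes called doublets in the titled positive library, 288 (96%) had UMIs of at least 3 carcinoma markers, and 154 of these also had 4 myeloid genes, against 0 of the 600 called in the titled control library. Among the kept titled positive cells 76.9% had 3 carcinoma markers.

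Carcinoma-like cells were found in the library whose treatment field says without metastasis. They were 55.7% of it, against 0.0102% of the library whose field says with metastasis. A loss of carcinoma cells from the titled control library in filtering or doublet removal was argued against, since 0% of its 611 left-out barcodes carried 3 carcinoma markers. An exchange of the titles alone cannot account for it, since it would leave both shares under the same treatment fields. An exchange of the treatment fields or the matrices stays open and was not tested, since the shares that raise the question cannot also test it and no other label tells the animals apart.

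The ribosomal protein list had a median above 0 in all 6 classes, though in 3 classes some members were lower. Free RNA of the carcinoma-like cells could account for part of this. With the estimated share subtracted, the median over classes was 0.17 (from 0.29), which lay within the counting half-width of 0.0575 around 0.14, the point at which the pattern would be halved, and the oligodendrocyte-like median turned to -0.75. The margin for counting error was added after that value was seen, and without it 0.17 would have counted against free RNA. Neither a difference between the library preparations, which cannot be told apart from the groups since each is 1 library (class medians spanned 0.39), nor a biological difference was excluded.

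Homeostatic genes were lower in microglia-like cells of the titled positive library. Monocytes counted among these cells would need to make up 87.8% of the RNA to lower the genes by that much, while monocyte markers stood at a median of 4.57% of the monocyte or macrophage-like level (2.39% for F10 to 76.0% for Ms4a4c, with Lyz2 at 18.1%). This reaches only monocytes that carry these markers. Macrophages that lack most of them were not tested and stay open, and the titled positive cluster scored 2.18 for microglia and 2.01 for monocyte markers. For free RNA of other cells, the median was -2.98 after subtraction and -3.04 before. The estimated shares (15.9% of the titled positive and 9.20% of the titled control class RNA) are too small to account for the fall. Shares of that size could not have halved the median in any case, so the subtraction adds nothing to this. A difference between the preparations or between the groups, in the state of microglia or in which of them were captured, stays open and was not tested.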

How the results depend on the processing

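Subtraction of the estimated free RNA and shares among cells other than carcinoma-like ones were chosen after the data had been seen, and the other alternatives before. Of 1123 values recomputed, 879 lay within the counting interval of the value reported, 235 lay outside it and 9 turned against an interval that excluded 0. These leave out the neutrophil lists of oligodendrocyte-like cells and the MHC class II list of T cell-like cells. Naming each cell by its own markers gave log2 ratios of shares of 7.99 for carcinoma-like (11.83 with clusters), -3.11 for microglia-like (-1.99), -2.29 for oligodendrocyte-like (-2.16) and -2.86 for endothelial cell-like cells (-2.38), and turned fibroblast-like cells from -0.52 to 0.94. Shares among cells other than carcinoma-like ones turned fibroblast-like cells too (0.66), and gave -0.82 for microglia-like, -0.99 for oligodendrocyte-like, -5.41 for astrocyte-like (-6.58), -1.20 for endothelial cell-like, 4.54 for monocyte or macrophage-like, 2.82 for T cell-like (1.64) and 5.67 for neutrophil-like cells (4.50). Without doublet removal the share ratio was -3.67 for microglia-like and -2.02 for oligodendrocyte-like cells, and the list medians -1.10 (myelin), -2.46 (homeostatic) and -0.41 (blood-brain barrier). The stricter filter gave 3.88 for monocyte or macrophage-like cells (3.36). Mean per-cell CPM gave 5.62 for oligodendrocyte interferon genes, -0.91 (myelin), 1.92 (tumour-associated macrophage), -0.57 (barrier) and -0.61 (cytotoxicity). Thinning to 1000 UMIs gave -3.34 (homeostatic), -0.60 (barrier) and -0.57 (cytotoxicity). Median-of-ratios scaling gave -0.76 (myelin) and turned mitochondrial transcripts of monocyte or macrophage-like cells from -0.10 to 0.042, by the all-gene shift of -0.14. Free RNA at 5% gave 6.48 (oligodendrocyte interferon) and -0.92 (myelin). The estimated share gave 6.97 (oligodendrocyte interferon), -0.76 (myelin), -0.30 (barrier) and -0.064 (cytotoxicity), turned oligodendrocyte proliferation (-0.54), glycolysis (-0.11) and ribosomal (-0.75) and T cell interferon genes (-0.17), and turned Sparcl1 (3.12) and Cryab (3.22) in T cell-like cells. After it, 13 of the 60 named gene and class pairs had no counts left and no value. Cells with carcinoma markers were 0% of the titled control library with 5 markers and 0% when thinned, and 49.8% and 41.3% of the titled positive library. Genes per cell had a ratio of 1.02 at 2000 and 1.04 at 500 UMIs, against 1.03 at 1000. Apart from the all-gene shift, the cause was not tested. No paired analysis was possible because each group has 1 library, for which leaving out a replicate and other splits were not possible either. The smallest class sums, where depth limits most, were titled control T cell-like (349384 UMIs), titled control fibroblast-like (521996) and titled positive fibroblast-like cells (658526).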

Other observations

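The genes in this part were chosen after their values were seen. Within the titled positive library, carcinoma-like cells held more RNA of all 14 proliferation genes than the pooled other cells. The mitotic kinase gene Cdk1 was at 375 against 101 CPM and Top2a at 319 against 115 CPM. All 11 MHC class I genes were lower in carcinoma-like cells, with H2-K1 at 4049 and 4210.4 CPM. Glycolysis and hypoxia genes went both ways, with Vegfa at 21.2 against 84.3 CPM and Car9 at 90.3 against 23.1 CPM. Lcn2, which encodes the iron-trafficking protein lipocalin 2, was at 14376 CPM in 37 titled positive ependymal cell-like cells (95% interval 13858 to 14909) and 1178 CPM in 160 titled control ones, above the 2369 CPM of carcinoma-like cells. In astrocyte-like cells it was at 2054 CPM (21 cells) and 7.97 CPM in the titled positive and titled control library. Carcinoma markers stood at 17.8% of the carcinoma-like level in titled positive astrocyte-like cells (0 to 100% by marker) and 15.7% in ependymal cell-like ones. Part of the Lcn2 there can therefore be free RNA.

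Xist, the RNA that silences an X chromosome in female cells, was at 139 CPM in the titled control library (95% interval 136 to 142). In the titled positive library it was at 2.002 CPM in carcinoma-like cells and 47.9 CPM in all others, including 68.4 CPM in microglia-like cells against 192 CPM in titled control microglia-like cells. The Y-linked genes Ddx3y, Eif2s3y and Uty had 0 UMIs in the titled control library and 3, 1 and 2 UMIs in the titled positive library. Haemoglobin genes took 0.0659% of UMIs in the titled control and 0.000158% in the titled positive library, and 12 and 0 barcodes held over 10% of them.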
